A study of Mus musculus with 14 samples.

How the data were processed

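The values used were whole-number read counts per gene from bulk RNA sequencing, in 2 deposited tables that the labels describe as raw counts. One table held the thymic libraries and the other the NK1.1- ILTCk, NK1.1+ ILTCk and PD1+ Tconv libraries, called the tumour table here, each with 50508 mouse gene symbols. The aligner, the counting program and the annotation behind these counts are not given in the sources used here. Per the submitters' processing notes, the genome was mm10 and the authors tested for differences with DESeq, whose version is not stated. The same notes name Cell Ranger 3.0.2 and Seurat 2.3.4 for the single-cell libraries, which were not analysed here. The mitochondrial genes held 0 counts in every library, so no mitochondrial share could be given.

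All tests were computed anew from the counts. Each table was fitted separately, because the thymic and tumour libraries share no sample. Genes were kept with filterByExpr, libraries were scaled with TMM, and edgeR's quasi-likelihood test (glmQLFit with robust estimation) gave log2 fold changes and Benjamini-Hochberg adjusted p-values. A gene was called at an adjusted p under 0.05 with no minimum fold. The tumour comparisons drew their spread from all 6 libraries of that table. Levels are CPM scaled by TMM, given as mean ± SD of 2 libraries; log2 fold changes are given ± standard error. A fold against a group with 0 counts is a bound with 3 counts set over the group, and intervals around ratios of few counts and segment shares cover counting error only.

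The comparisons, the gene lists, the cell type markers, the tests and the rule for naming genes were chosen before the data were examined. The named genes were Klrb1c, Pdcd1, Fcer1g, Cd4, Cd8a, Cd8b1 and Cd5 whatever their result, up to 8 genes per direction with the largest called change, a mean logCPM of at least 4 and libraries that did not overlap between groups, and up to 4 members of each described list with the smallest adjusted p. That rule left out receptor and immunoglobulin segments, predicted and Rik genes, and mitochondrial and ribosomal protein genes. After the data were examined, a further part was added for the tumour comparisons, where edgeR called no gene: the 8 highest and 8 lowest DESeq2 calls under the same conditions. Gzmb, Il2rb, Ikzf2, Tyrobp, Trdc and some other members of the lists were also named after their values were seen.

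The 28 lists covered NK receptors; ITAM adaptors and proximal kinases; cytotoxic effectors; exhaustion and inhibitory receptors; tissue residency; naive and recirculation genes; TCR-induced and agonist selection genes; lineage transcription factors; the TCR complex and coreceptors. Further lists covered common gamma-chain cytokine signalling, cytokines and chemokines, chemokine and lipid trafficking receptors, cell cycle, interferon-stimulated genes, glycolysis and apoptosis regulators. The cell type lists were B cell, myeloid, dendritic cell and MHC class II, epithelial and mammary tumour, stromal and endothelial, erythroid, double-positive thymocyte, gamma-delta T cell, CD4 helper and regulatory T cell, natural killer T, and ILC and NK cell markers, with dissociation and heat stress genes. Each list with at least 5 measured members was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry from limma were the alternatives. Members were counted with p-values adjusted over all genes and, apart from that, with p-values adjusted over the list alone.

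Alternatives for the gene tests were RLE and upper-quartile scaling, DESeq2, limma-voom, no filter on low counts, at least 50 counts in 2 libraries, the replicate number as a block, glmTreat against 1.5-fold, the 4 compared tumour libraries alone, and each library left out in turn. A restriction of the tumour comparisons to genes with at least 10 CPM on average in the thymus was added after the data were examined. Overlap of calls between the tables was tested with Fisher's exact test, two-sided. Gene coordinates came from GENCODE release M21 on GRCm38, where 47653 of the symbols were found.

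The tests were tested on simulated data with the depth and spread of each table. In the simulated thymic table edgeR recovered 1.49% of genes changed 2-fold, 29.9% changed 4-fold and 57.6% changed 8-fold. In the simulated tumour table it recovered 0, 0 and 9.09%, with 0 false calls. DESeq2 recovered 5.97, 20.9 and 72.7% in the tumour table, but 49 of its 115 calls were false there, and 40 of 140 in the thymic table. At each fold 66 or 67 genes were changed, of 14634 in the thymic and 18091 in the tumour table. Recovery and the share of false calls depend on how many genes change, which is not known for the real tables. A simulated list of 20 genes changed 4-fold was called by camera with the preset correlation in both tables. With an estimated correlation its adjusted p was 0.0954 in the thymic and 0.0491 in the tumour table. In the thymic table that setting thus missed a simulated change, and in the tumour table it narrowly found one. The simulated genes varied independently of each other, close to what the preset correlation assumes. The simulation therefore cannot tell how often the preset correlation calls lists of co-regulated genes falsely. It gives no ground to discount a call lost with an estimated correlation.

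Computations ran in R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.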

Results

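The data were bulk RNA-sequencing libraries of mouse T cells from a study of αβ innate-like T cells with killer function (ILTCk), self-reactive cells found in tumours, and of their thymic progenitors (ILTCkP). There were 5 groups of 2 libraries each. CD8SP (CD8 single-positive thymocytes) and ILTCkP came from the thymus. NK1.1- ILTCk, NK1.1+ ILTCk and PD1+ Tconv (conventional T cells carrying PD-1) came from mice labelled retrogenic, that is, rebuilt from blood stem cells given an introduced T cell receptor (TCR). Per the labels' protocols, the NK1.1+ ILTCk and PD1+ Tconv cells were sorted from tumours as TCRβ+ CD8α+ cells, the former PD-1-negative and the latter PD-1-positive and NK1.1-negative. The thymic progenitors did not bind the CD1d tetramer that marks natural killer T cells. The gate, tissue and tumour model of the NK1.1- group are not given in the sources used here, so its origin from tumours is assumed from the table it shares with the other two. The characteristics of both ILTCk groups give their cell type as ILTCkP while the titles say ILTCk; the titles were followed. The 4 single-cell libraries of tumour-infiltrating T cells in the same series were not analysed here.

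Total counts were 28274718 and 30141711 in CD8SP and 27826979 and 32097301 in ILTCkP. They were 28044732 and 22153656 in NK1.1- ILTCk, 19837739 and 25058242 in NK1.1+ ILTCk, and 28097845 and 16530085 in PD1+ Tconv. Between 17741 and 24559 genes were detected per library. Log2 CPM correlated between replicates with Pearson coefficients across genes of 0.975 in CD8SP, 0.938 in ILTCkP, 0.933 in NK1.1- ILTCk, 0.911 in NK1.1+ ILTCk and 0.877 in PD1+ Tconv. Genes are not independent replicates. The labels call the libraries biological replicates but do not state separate animals, so p-values measure only the spread between these samples, which may be technical. Gene coordinates are on GRCm38. Genes behind the sorts were Klrb1c (NK1.1, chromosome 6, 128778485 to 128789215) and Pdcd1 (PD-1, chromosome 1, 94038305 to 94052553). Fcer1g (the ITAM adaptor FcRγ, chromosome 1, 171229572 to 171234365) is part of no gate described here. The coreceptor and TCR-signal genes were Cd8a (chromosome 6, 71373427 to 71379173), Cd8b1 (chromosome 6, 71322788 to 71337494), Cd4 (chromosome 6, 124864692 to 124888221) and Cd5 (chromosome 19, 10717116 to 10739002).

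The first comparison asked how the thymic progenitors of ILTCk differ from conventional CD8 thymocytes. Fcer1g, which encodes a signalling adaptor usually found in NK and myeloid cells, rose by a log2 fold change of 7.12 ± 0.30 in ILTCkP (202 ± 26.2 against 1.45 ± 0.0989 CPM, n = 2 each, adjusted p = 0.00201). Pdcd1 rose by 5.66 ± 0.24 (1297 ± 39.5 against 25.6 ± 1.81 CPM, adjusted p = 0.00201), and Klrb1c rose by 4.53 ± 0.74 from a low level (12.1 ± 4.12 against 0.524 ± 0.428 CPM, adjusted p = 0.0320). The coreceptor genes were low in ILTCkP, whose gate took cells negative or dull for CD4 and CD8α; the rest of that gate, and so whether PD-1 was part of it, is not given in full in the sources used here. Cd8b1 fell by 8.28 ± 0.37 (9.10 ± 2.78 against 2830.4 ± 300.5 CPM, adjusted p = 0.00208) and Cd8a by 6.32 ± 0.52 (24.7 ± 14.3 against 1979 ± 194 CPM, adjusted p = 0.00626). Cd4 stood at 21.4 against 9.55 CPM (1.17 ± 0.55, adjusted p = 0.282) and Cd5 at 324 ± 153 against 444 ± 6.76 CPM (-0.45 ± 0.35, adjusted p = 0.491), neither past the threshold. Without ILTCkP replicate 1 the value of Cd5 was -1.03 (adjusted p = 0.000219).

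Among 14634 tested genes edgeR called 495 higher and 194 lower in ILTCkP, all of them at least 2-fold. DESeq2 called 1333 higher and 697 lower, edgeR 2812 in all without ILTCkP replicate 1 and 7017 without ILTCkP replicate 2, each of them including nearly all of the 689. Without CD8SP replicate 1 edgeR called 670, of which 468 were among the 689, and without CD8SP replicate 2 it called 592, of which 447 were. Zbtb16 (chromosome 9, 48654297 to 48836222), which encodes PLZF, a transcription factor of innate-like lymphocytes, had 171 ± 134 CPM in ILTCkP and 0 counts in CD8SP, at least 3214-fold higher (adjusted p = 0.0116). Ptpn5, a phosphatase gene, stood at 163 ± 7.74 CPM (at least 3281-fold, adjusted p = 0.00208) and the NK receptor gene Klrb1a at 72.3 ± 45.9 CPM (at least 1542-fold, adjusted p = 0.0102), both against 0 counts. Ccr10, a skin- and mucosa-homing receptor gene (149 against 0.127 CPM), Tnni1 (487 against 0.457), Itgb8 (32.1 against 0.0805), Prr5l (275 against 0.920) and Nrgn (766 against 2.61) rose by log2 fold changes of 8.19 to 10.11. Il2rb (chromosome 15, 78479256 to 78495271), the β chain of the receptors for IL-2 and IL-15, rose by 3.52 ± 0.22, to 5057 ± 358 against 439 ± 6.13 CPM (adjusted p = 0.00329). Beside both CD8 genes, the largest falls were in Acvrl1, Ppp1r1b, Gpr83, Slc16a5, Ms4a4c and the thymic homing receptor gene Ccr9, from -6.43 ± 1.19 to -4.70 ± 0.26; Acvrl1 (adjusted p = 0.0441) did not pass with DESeq2 (adjusted p = 0.0668).

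**Figure D1:**
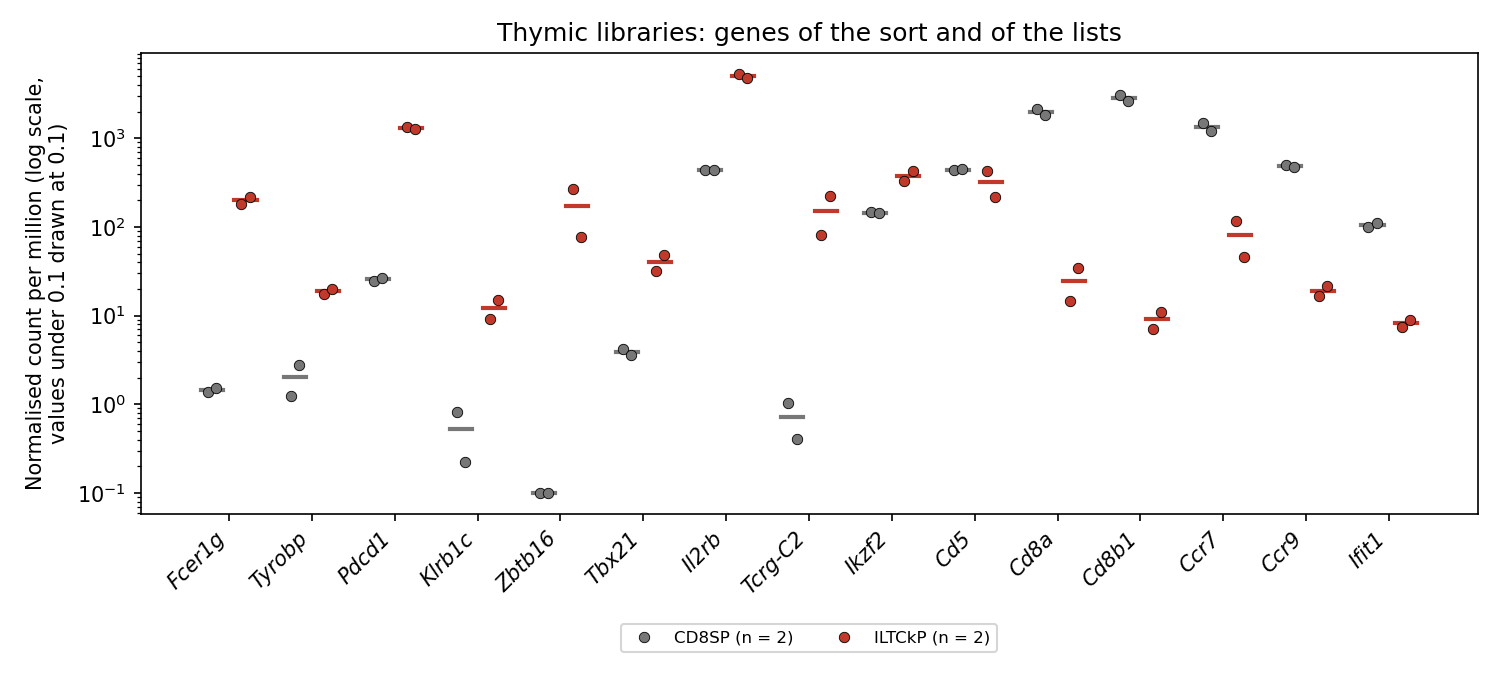
Normalised CPM (log scale) of 15 genes in CD8SP and ILTCkP; points are libraries, bars are means of 2 libraries, and values under 0.1 are drawn at 0.1. Fcer1g stood at 202 against 1.45 CPM, Il2rb at 5057 against 439 and Cd8b1 at 9.10 against 2830.4.

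NK-type receptor and signalling genes were raised as groups. Of 16 measured NK receptor genes 7 rose and 1 fell, 13 and 1 when adjusted over the list alone, with a median log2 fold change of 3.50, or 3.31 with Klra9, at 0 counts in CD8SP, set to its bound (adjusted p = 1.65e-08, and adjusted p = 0.290 with an estimated correlation). Cd244 rose by 5.57 ± 0.68 (47.4 against 0.985 CPM, adjusted p = 0.0142) and Cd160 by 2.78 ± 0.26 (505 against 73.7 CPM, adjusted p = 0.00788), while Cd226, an activating receptor gene, fell by 4.00 ± 0.45 (6.49 against 105 CPM, adjusted p = 0.0114). Of 18 ITAM adaptor and proximal kinase genes 5 rose and none fell (median 0.36, adjusted p = 3.15e-06, and adjusted p = 0.161 with an estimated correlation): Fcer1g, Lat2 (6.96 ± 0.35; 108 against 0.862 CPM), Plcg2 (4.93 ± 0.40; 146 against 4.79 CPM), Sh2d1b1 (at least 83.3-fold) and Tyrobp, the DAP12 adaptor gene (3.22 ± 0.51; 18.8 against 2.01 CPM, adjusted p = 0.0292). The cytotoxic effector list did not move as a group (1 of 16 rose and 1 fell, median 0.27, adjusted p = 0.373), and Gzmb stood at 9.59 against 3.33 CPM (1.53 ± 0.43, adjusted p = 0.110).

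Genes of strong TCR signalling and of inhibition were higher in ILTCkP. Of 16 exhaustion and inhibitory receptor genes 7 rose and none fell (median 1.61, adjusted p = 2.46e-14, and adjusted p = 0.158 with an estimated correlation), with Lag3 at 13.4 against 0.0661 CPM (7.58 ± 0.57), Tigit at 65.3 against 2.94 CPM (4.47 ± 0.43) and Entpd1, the CD39 gene, at 25.8 against 1.95 CPM (3.73 ± 0.40). Of 26 TCR-induced and agonist selection genes 9 rose and 2 fell (median 0.89, adjusted p = 3.08e-05, and adjusted p = 0.161 with an estimated correlation). Nr4a2 rose by 3.12 ± 0.43 (44.4 against 5.09 CPM, adjusted p = 0.0191), and Egr2 by 1.84 ± 0.22 (160 against 44.6 CPM, adjusted p = 0.0121; 0.0885 without CD8SP replicate 2). Ikzf2, which encodes Helios, a marker of agonist-selected thymocytes, rose by 1.37 ± 0.23 (377 against 145 CPM, adjusted p = 0.0328), a call lost without CD8SP replicate 1 (adjusted p = 0.197) or CD8SP replicate 2 (adjusted p = 0.240). Of 26 lineage transcription factor genes 7 rose and 2 fell (median 1.14, adjusted p = 4.02e-05, and adjusted p = 0.229 with an estimated correlation). Besides Zbtb16, Tbx21 (T-bet) rose by 3.35 ± 0.38 (40.0 against 3.91 CPM) and Zbtb7b by 7.56 ± 0.88, while Bcl11b, a T-lineage identity factor gene, fell by 2.59 ± 0.24 (26.2 against 158 CPM).

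The naive and recirculation, interferon-stimulated, TCR complex and cell cycle lists were lower by camera at the preset correlation. None of 19 naive and recirculation genes rose and 7 fell, and all 19 had negative values (median -0.77, adjusted p = 1.46e-12, and adjusted p = 0.158 with an estimated correlation). Ccr7 fell by 4.04 ± 0.50 (81.8 against 1340.45 CPM) and Satb1 by 2.74 ± 0.25. Of 28 interferon-stimulated genes 16 fell and none rose (median -1.69, adjusted p = 2.37e-20, and adjusted p = 0.158 with an estimated correlation), with Ifit1 at 8.25 against 105 CPM (-3.67 ± 0.28), Rtp4 at 42.0 against 198 CPM (-2.24 ± 0.22) and Oas2 at 1.45 against 26.8 CPM (-4.22 ± 0.45). Of 18 TCR complex and coreceptor genes 4 fell and none rose (median -0.27, adjusted p = 4.18e-06, and adjusted p = 0.250 with an estimated correlation). These included Cd8a and Cd8b1, whose fall followed from the gate, and Thy1 at 12.3 against 113 CPM (-3.20 ± 0.56). The list was not tested without the CD8 genes. Of 30 cell cycle genes 3 fell (median -0.38, adjusted p = 0.000556, and adjusted p = 0.414 with an estimated correlation); Top2a fell by 1.54 ± 0.26 (187 against 546 CPM, adjusted p = 0.0334), a call lost without either CD8SP library (replicate 1 adjusted p = 0.0677, replicate 2 adjusted p = 0.0649). Glycolysis genes were higher, with 2 of 16 called, Tpi1 (1.89 ± 0.25; 836 against 226 CPM) and Slc16a3 (3.42 ± 0.55), a median of 0.70 and adjusted p = 0.000271 (adjusted p = 0.505 with an estimated correlation).

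Some genes listed as markers of other T cell lineages were higher in ILTCkP. Of 7 gamma-delta T cell markers 4 rose (median 5.03, adjusted p = 8.95e-09, and adjusted p = 0.158 with an estimated correlation): the γ-chain constant genes Tcrg-C2 (152 ± 100 against 0.723 CPM, 7.72 ± 0.77), Tcrg-C4 (6.81 ± 0.82) and Tcrg-C1 (5.03 ± 0.69), and Blk (6.17 ± 0.81). Trdc, the δ constant gene, stood at 45.8 against 15.3 CPM (1.58 ± 0.34, adjusted p = 0.0629). The γ-chain genes alone do not show gamma-delta T cells. PD1+ Tconv, sorted as TCRβ+ cells, held Tcrg-C2 at 752 and 380.5 CPM and Tcrg-C4 at 211 and 109 CPM. Of 8 CD4 helper and regulatory T cell markers 3 rose (median 1.06, adjusted p = 0.00388, and adjusted p = 0.414 with an estimated correlation, and 0.141 without ILTCkP replicate 1), and of 7 natural killer T and other innate-like markers 2 rose and 1 fell (median 1.54, adjusted p = 0.0218, and adjusted p = 0.414 with an estimated correlation). The remaining lists did not pass. Medians were 0.13 for tissue residency (1 of 15 up, 2 down; mean 0.03, test direction down, adjusted p = 0.321), 0.15 for gamma-chain cytokine signalling (1 of 21 up, Il2rb; 0.223), 0.24 for cytokines and chemokines (3 of 12 up; 0.103), 0.53 for chemokine receptors (3 of 19 up, 2 down; 0.132) and 0.27 for apoptosis regulators (3 of 17 up; 0.304). For cells outside the sort, medians were 1.95 for B cell (1 of 8 up, Blk; adjusted p = 0.0746), 0.25 for myeloid (1 of 10 down; 0.528), 0.48 for dendritic cell and MHC class II (0 of 9; 0.589), -0.45 for double-positive thymocyte (1 of 12 down, Rag1; 0.257), and 1.54 for ILC and NK cell markers (2 of 5 up, 1 down; 0.223). Stress genes had a median of 0.03 (0 of 18 called; adjusted p = 0.819). The epithelial, stromal and erythroid lists had 4 measured members each, none called, too few to test.

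**Figure D2:**
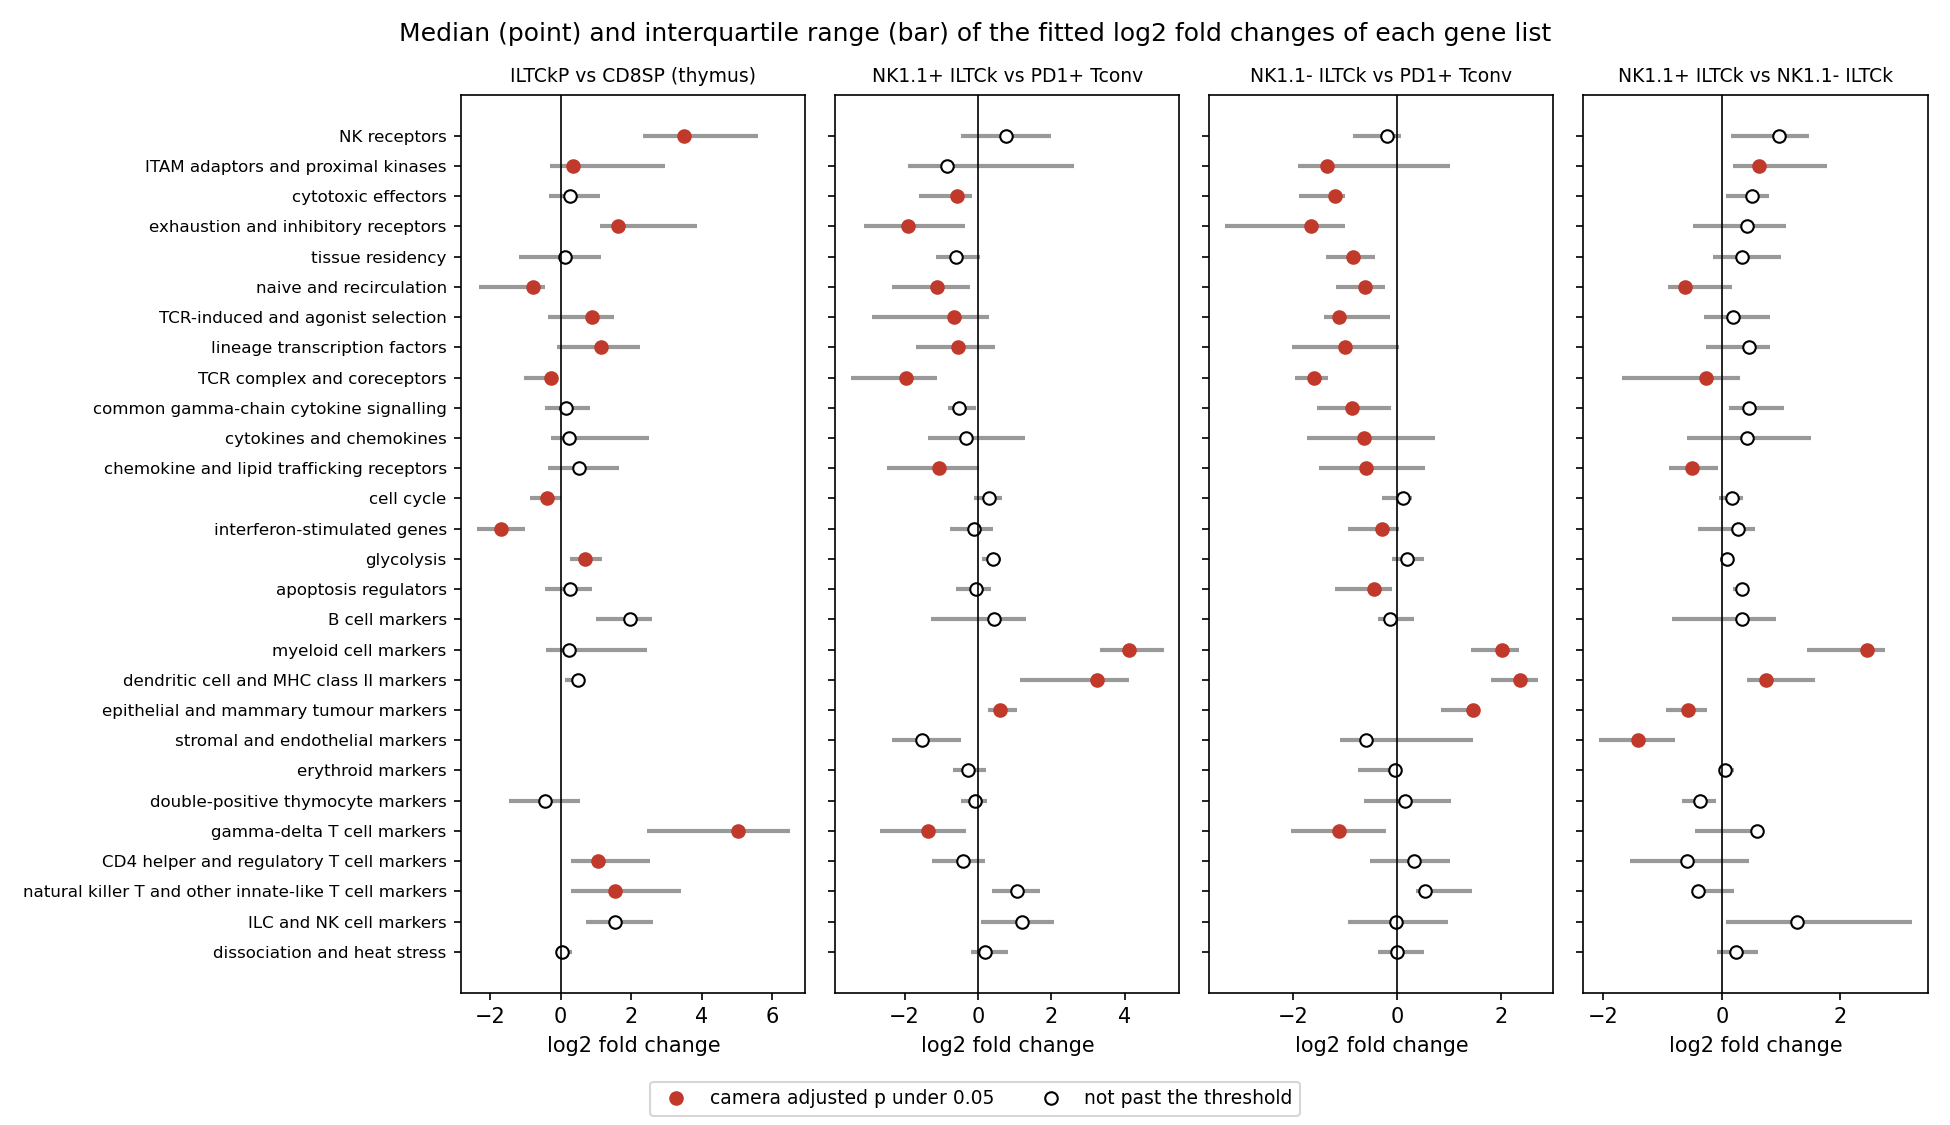
Median log2 fold change of each gene list (points; bars are interquartile ranges, filled points passed camera) in the thymic and tumour comparisons, blank where fewer than 5 members were measured. NK receptors reached 3.50 in the thymus, and myeloid markers 4.11 in NK1.1+ ILTCk against PD1+ Tconv.

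The second comparison asked how NK1.1+ ILTCk differ from PD1+ conventional T cells among tumour-infiltrating CD8α+ cells. Of the genes of the sort, Pdcd1 stood at 6.24 ± 1.67 CPM in NK1.1+ ILTCk and 636 ± 166 in PD1+ Tconv (log2 fold change -6.67 ± 0.57, n = 2 each, edgeR adjusted p = 0.0725, DESeq2 adjusted p = 5.24e-32), and Klrb1c at 189 ± 170 against 20.9 ± 26.3 CPM (3.17 ± 1.28, adjusted p = 0.334, DESeq2 0.0485). Fcer1g stood at 1337 ± 153 against 132 ± 72.6 CPM (3.34 ± 0.56, adjusted p = 0.0942, DESeq2 6.63e-07). Cd8b1 was at 27.5 ± 10.4 against 801 ± 112 CPM (-4.86 ± 0.53, adjusted p = 0.0725, DESeq2 1.38e-17), while Cd8a was at 517 ± 524 against 1101 ± 413 CPM (-1.09 ± 0.82, adjusted p = 0.603). The granzyme gene Gzmk, a mark of antigen-experienced CD8 T cells, was at 2.71 ± 1.47 against 381 ± 70.2 CPM (-7.13 ± 0.68, adjusted p = 0.0725, DESeq2 2.81e-28).

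Cd5, whose level follows the strength of TCR signals, stood at 4.07 ± 3.40 against 69.3 ± 32.3 CPM (-4.09 ± 0.74, adjusted p = 0.106, DESeq2 2.10e-06). Cd4 stood at 9.97 against 11.3 CPM (-0.19 ± 1.00, adjusted p = 0.957), and its sign turned without NK1.1+ ILTCk replicate 2 (0.29) or PD1+ Tconv replicate 1 (2.63). Gzmb, the main killing enzyme gene, stood at 1755 ± 1723 against 874 ± 859 CPM (1.01 ± 1.02, adjusted p = 0.716; -0.70 without NK1.1+ ILTCk replicate 1). In edgeR none of 18091 tested genes passed, with 2590 at an unadjusted p under 0.05 where 905 are due by chance; DESeq2 called 637 higher and 557 lower, and limma-voom 3 lower, Pdcd1 (adjusted p = 0.0473), Cd8b1 (0.0476) and Gzmk (0.0476). Without NK1.1+ ILTCk replicate 1 edgeR called 35, among them Gzmk, Eomes and Csf1r. The highest DESeq2 calls were macrophage-type genes, among them Folr2 (10.03 ± 2.23), Retnla (9.38 ± 1.15; 2140.3 against 3.26 CPM) and Ccl8 (8.76 ± 2.58). The lowest included Gzmk, Pdcd1 and Themis (-5.82 ± 0.97; 2.84 against 160 CPM), and gland genes such as Bpifa2 (-7.99 ± 3.13) that were abundant in PD1+ Tconv replicate 2.

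As groups, myeloid and antigen-presentation transcripts were higher and conventional T cell transcripts lower in NK1.1+ ILTCk. Adjusted over the list alone, 11 of 14 myeloid markers rose (median 4.11, adjusted p = 1.32e-17, and adjusted p = 0.493 with an estimated correlation), with Csf1r at 1092 ± 569 against 17.2 ± 4.602 CPM (5.99 ± 0.71) and C1qa at 1316 ± 860 against 33.7 ± 32.1 CPM (5.29 ± 0.96). Of 10 dendritic cell and MHC class II markers 6 rose when adjusted over the list alone (median 3.24, adjusted p = 9.97e-07, and adjusted p = 0.602 with an estimated correlation), H2-Aa standing at 3189.8 against 208 CPM. Of 18 TCR complex and coreceptor genes 9 fell when adjusted over the list alone (median -1.97, adjusted p = 7.48e-17, and adjusted p = 0.491 with an estimated correlation), with Icos at 7.54 against 107 CPM (-3.83 ± 0.48) and Cd28 at 11.1 against 214 CPM (-4.26 ± 0.56). Of 18 exhaustion genes 7 fell when adjusted over the list alone (median -1.92, adjusted p = 2.65e-08, and adjusted p = 0.511 with an estimated correlation), with Nr4a2 at 33.7 against 303 CPM and Ctla4 at 5.42 against 87.8 CPM. This list and the agonist selection list hold Pdcd1, and the groups were gated PD-1-negative and PD-1-positive. Neither list is thus independent of the sort. Naive and recirculation genes had a median of -1.11 (adjusted p = 1.38e-05, and adjusted p = 0.491 with an estimated correlation) and agonist selection genes -0.66 (adjusted p = 2.83e-05, and adjusted p = 0.491 with an estimated correlation).

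Cytotoxic effectors were lower (median -0.57, adjusted p = 0.000450), as were chemokine receptors (median -1.05, adjusted p = 0.000639), lineage transcription factors (median -0.53, adjusted p = 0.00995) and gamma-delta T cell markers (median -1.37, adjusted p = 0.0275). Epithelial markers were higher (median 0.59, adjusted p = 0.0412). Without PD1+ Tconv replicate 1 all 5 calls were lost, with adjusted p-values of 0.313, 0.113, 0.134, 0.169 and 0.334 in that order. Cytotoxic effectors (0.0986) and gamma-delta markers (0.0709) also lost theirs without NK1.1+ ILTCk replicate 2, and epithelial markers (0.102) without NK1.1+ ILTCk replicate 1. The 5 lists had adjusted p = 0.605 to 0.726 with an estimated correlation. These levels do not allow for the lower CD3 and TCR constant genes of NK1.1+ ILTCk. Relative to those genes Gzmb stood at mean log2 ratios (± SD) of 3.02 ± 0.16 in NK1.1+ ILTCk and 0.41 ± 1.29 in PD1+ Tconv. The other cytotoxic effectors were not put on that scale. NK receptors had a median of 0.76 (0 of 23 up, adjusted p = 0.277); Ncr1, the NKp46 gene, stood at 22.6 ± 21.8 against 0.987 ± 1.40 CPM (4.42 ± 1.51, adjusted p = 0.274). ITAM adaptors had a median of -0.84, a mean of 0.20 and an upward test (adjusted p = 0.994), Sh2d1a (4.17 against 91.8 CPM) and Fcgr3 (460 against 11.2 CPM) lying at opposite ends. The other 15 lists did not pass, among them stromal (median -1.51, adjusted p = 0.0561) and erythroid markers (median -0.27 with an upward test, adjusted p = 0.585). Cytokines (median -0.33, mean 0.12, test down) and B cell markers (median 0.42, mean -0.07, test up) differed in sign between measures.

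**Figure D3:**
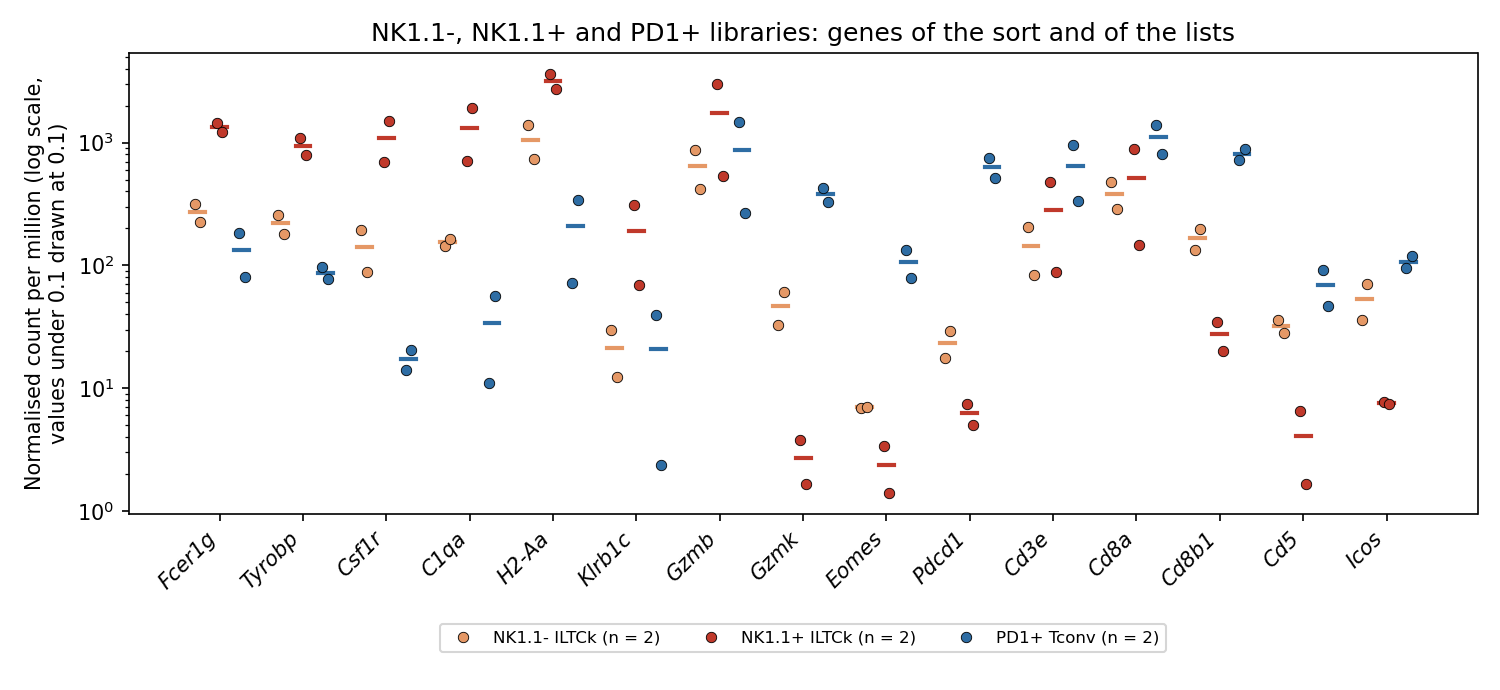
Normalised CPM (log scale) of 15 genes in NK1.1- ILTCk, NK1.1+ ILTCk and PD1+ Tconv; points are libraries and bars are means of 2 libraries. Csf1r stood at 141, 1092 and 17.2 CPM in that order, and Pdcd1 at 23.5, 6.24 and 636 CPM.

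The third comparison asked how ILTCk labelled NK1.1- differ from PD1+ Tconv. Pdcd1 stood at 23.5 ± 8.12 against 636 ± 166 CPM (-4.76 ± 0.52, n = 2 each, edgeR adjusted p = 0.285, DESeq2 1.03e-15), Eomes, a CD8 memory factor gene, at 6.98 ± 0.134 against 106 ± 39.0 CPM (-3.93 ± 0.56, adjusted p = 0.285) and Tox, a factor gene of exhausted T cells, at 14.2 ± 11.4 against 232 ± 90.9 CPM (-4.02 ± 1.04, adjusted p = 0.354). Cd8b1 stood at 167 ± 46.1 against 801 ± 112 CPM (-2.26 ± 0.47, adjusted p = 0.344, DESeq2 0.00159) and Cd8a at 382 ± 134 against 1101 ± 413 CPM (-1.53 ± 0.83, adjusted p = 0.497). Fcer1g was at 272 ± 65.6 against 132 ± 72.6 CPM (1.04 ± 0.52, adjusted p = 0.467), Cd5 at 31.9 against 69.3 CPM (-1.12 ± 0.66, adjusted p = 0.534) and Cd4 at 32.3 against 11.3 CPM (1.504 ± 1.01, adjusted p = 0.590). Klrb1c averaged 21.2 ± 12.4 against 20.9 ± 26.3 CPM (0.01 ± 1.18, adjusted p = 0.998), with PD1+ Tconv libraries far apart. Its value was -0.76 without NK1.1- ILTCk replicate 1, 0.52 without NK1.1- ILTCk replicate 2, 3.19 without PD1+ Tconv replicate 1 and -0.90 without PD1+ Tconv replicate 2. Gzmb stood at 646 ± 323 against 874 ± 859 CPM (-0.44 ± 1.01, adjusted p = 0.900; 0.02 without NK1.1- ILTCk replicate 2 and 1.30 without PD1+ Tconv replicate 1).

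In edgeR none of 18091 genes passed in NK1.1- ILTCk against PD1+ Tconv, with 2147 at an unadjusted p under 0.05, and limma-voom called 0; DESeq2 called 346 higher and 261 lower. The highest DESeq2 calls included the macrophage-type genes Retnla (7.91 ± 1.08; 772 against 3.26 CPM) and Mrc1 (5.20 ± 1.22), the lowest Pdcd1, Tox, Eomes, Tigit (-3.34 ± 0.95) and Nr4a2 (-3.20 ± 0.48; 32.9 against 303 CPM). Adjusted over the list alone, 7 of 18 exhaustion genes fell (median -1.64, adjusted p = 9.52e-11), 4 of 18 TCR complex genes (median -1.60, adjusted p = 4.29e-09) and 4 of 26 agonist selection genes (median -1.12, adjusted p = 6.34e-06). The exhaustion and agonist selection lists hold Pdcd1, and PD1+ Tconv were gated PD-1-positive, so neither is independent of the sort. Of 26 transcription factor genes 6 fell and 3 rose when adjusted over the list alone (median -0.99, adjusted p = 0.000251). Myeloid markers (median 2.02, adjusted p = 1.26e-08), MHC class II markers (median 2.37, adjusted p = 6.43e-05) and epithelial markers (median 1.46, adjusted p = 1.92e-05) were higher, Csn3, a milk protein gene, standing at 4777 ± 3511 against 996 ± 807 CPM. Each of these 7 lists had adjusted p = 0.479 with an estimated correlation. A further 10 lists passed downward, with adjusted p-values from 6.34e-06 for cytotoxic effectors (median -1.18) to 0.0420 for apoptosis regulators (-0.45), of which each lost its call without at least 1 library. Without PD1+ Tconv replicate 1 these were cytotoxic effectors (0.0947), naive genes (0.0947), gamma-chain signalling (0.168), residency (0.863), chemokine receptors (0.570), ITAM adaptors (0.633), apoptosis regulators (0.489) and gamma-delta markers (0.148). Without NK1.1- ILTCk replicate 2, residency (0.0631), chemokine receptors (0.199), ITAM adaptors (0.476), apoptosis regulators (0.136) and gamma-delta markers (0.0594) did not pass. Cytokines (0.0205) reached 0.0656 without NK1.1- ILTCk replicate 1 and 0.0562 without PD1+ Tconv replicate 2, and interferon-stimulated genes (0.0227) reached 0.611 and 0.569, the former with the direction turned. The 10 lists had adjusted p = 0.479 to 0.839 with an estimated correlation. NK receptors had a median of -0.18, a mean of -0.20 and an upward test (adjusted p = 0.969).

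The fourth comparison asked how the ILTCk groups differ by NK1.1. Klrb1c stood at 189 ± 170 CPM in NK1.1+ and 21.2 ± 12.4 in NK1.1- ILTCk (3.16 ± 1.28, n = 2 each, edgeR adjusted p = 1.00, DESeq2 0.257). Fcer1g stood at 1337 ± 153 against 272 ± 65.6 CPM (2.30 ± 0.54, DESeq2 adjusted p = 0.0266) and Cd8b1 at 27.5 ± 10.4 against 167 ± 46.1 CPM (-2.60 ± 0.48, DESeq2 0.000832). Cd5 was at 4.07 against 31.9 CPM (-2.97 ± 0.71, DESeq2 0.0222), Pdcd1 at 6.24 against 23.5 CPM (-1.91 ± 0.46, DESeq2 0.0690) and Cd4 at 9.97 against 32.3 CPM (-1.69 ± 1.02, DESeq2 0.910). Cd8a stood at 517 ± 524 against 382 ± 134 CPM (0.44 ± 0.81; -1.38 without NK1.1+ ILTCk replicate 1), and Gzmb at 1755 ± 1723 against 646 ± 323 CPM (1.44 ± 1.03; -0.27 without NK1.1+ ILTCk replicate 1).

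In edgeR none of 18091 genes passed between the ILTCk groups, with 712 at an unadjusted p under 0.05, and limma-voom called 0; DESeq2 called 33 higher and 22 lower. The 33 included Cd5l (4.91 ± 0.99; 56.1 against 1.87 CPM), Siglec1 (4.83 ± 1.39) and C1qa (3.10 ± 0.86), all macrophage genes, and the 22 included Gzmk (-4.10 ± 0.59; 2.71 against 46.8 CPM), Icos (-2.82 ± 0.46), Cd28 (-2.29 ± 0.52) and Il7r (-1.92 ± 0.38). Of 14 myeloid markers 4 rose when adjusted over the list alone (median 2.45, adjusted p = 8.41e-12, and adjusted p = 0.758 with an estimated correlation), and stromal markers were lower (median -1.42, adjusted p = 9.56e-06, and adjusted p = 0.758 with an estimated correlation). TCR complex genes were lower (median -0.27, adjusted p = 1.14e-06, and adjusted p = 0.758 with an estimated correlation, and 0.493 without NK1.1+ ILTCk replicate 2). ITAM adaptors (median 0.62, adjusted p = 0.000759) and MHC class II markers (median 0.75, adjusted p = 0.0182) were higher. Naive genes (median -0.63, adjusted p = 0.00846), epithelial markers (median -0.57, adjusted p = 0.0182) and chemokine receptors (median -0.51, adjusted p = 0.0286) were lower. These 5 lists had adjusted p = 0.758 to 0.805 with an estimated correlation. Without NK1.1+ ILTCk replicate 1 the calls of ITAM adaptors (0.462), MHC class II markers (0.730), naive genes (0.774) and epithelial markers (0.139) were lost. Without NK1.1- ILTCk replicate 2 those of ITAM adaptors (0.0907), MHC class II markers (0.524) and epithelial markers (0.118) were lost. Naive genes (0.104) and chemokine receptors (0.350) did not pass without NK1.1- ILTCk replicate 1, nor chemokine receptors (0.489) without NK1.1+ ILTCk replicate 2. NK receptors had a median of 0.97 (adjusted p = 0.0791).

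Whether the thymic programme carried over into the tumour cells was asked by the overlap of calls. With the main edgeR fit, which had no replicate block, no overlap could be tested, since it called 0 genes in the tumour comparisons. Counts of shared calls with the block are given below. Among 14756 genes tested by DESeq2 in the thymus and in NK1.1+ ILTCk against PD1+ Tconv, 93 were higher in both, where independence gives 32.6 (Fisher's exact, adjusted p = 7.44e-21), and 118 lower in both, where it gives 22.1 (adjusted p = 1.28e-53). In opposite directions there were 35 against 41.8 (adjusted p = 0.381) and 15 against 17.2 (adjusted p = 0.707). For NK1.1- ILTCk against PD1+ Tconv 33 genes were higher in both against 14.0 (adjusted p = 5.65e-06) and 33 lower in both against 10.97 (adjusted p = 5.51e-08), but 34 higher in the thymus were lower in the tumour against 20.7 (adjusted p = 0.00463), with 6 against 7.42 the other way (adjusted p = 0.849). Log2 fold changes across 13821 genes correlated at a Pearson coefficient of 0.228 and a Spearman coefficient of 0.288 for NK1.1+ ILTCk, and 0.150 and 0.137 for NK1.1- ILTCk; genes are not independent replicates. By DESeq2 Fcer1g and Tyrobp were higher and Cd8b1 lower in ILTCkP and in NK1.1+ ILTCk alike, whereas Pdcd1 was higher in ILTCkP and lower in both ILTCk groups of the tumour table. For NK1.1+ ILTCk the Pdcd1 values say nothing on carry-over, since the gates took PD-1-negative cells there and PD-1-positive cells for PD1+ Tconv. Nor does the thymic fall of Cd8b1, since CD8SP cells were compared with cells gated negative or dull for CD4 and CD8α. Myeloid markers, which Fcer1g and Tyrobp accompany in myeloid cells, rose in NK1.1+ ILTCk as well (median 4.11).

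Receptor segment usage was described for each library. Clones were not read, and cells of different clones can share a segment. The effective number of Trbv segments was 10.4 to 13.6 in the thymic libraries and 12.1 to 12.8 in both ILTCk groups, and 6.95 and 5.66 in PD1+ Tconv. PD1+ Tconv replicate 1 held 25.2% Trbv13-1 (exact 95% interval 24.5 to 26.0%) and 19.5% Trbv15, and replicate 2 held 36.3% Trbv12-1 (34.7 to 38.0%). The most used Trbv segment took 12.02 to 17.2% elsewhere. Effective Trav numbers were 28.2 to 41.8 outside PD1+ Tconv and 8.48 and 14.7 within it, with Trav5-1 at 27.8% (26.6 to 28.9%) in replicate 1 and Trav14-1 at 18.6% (15.5 to 22.0%) in replicate 2; near-identical Trav copies make these shares uncertain. No single Trav or Trbv segment filled any library, although the labels call the mice of the tumour table retrogenic.

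**Figure D4:**
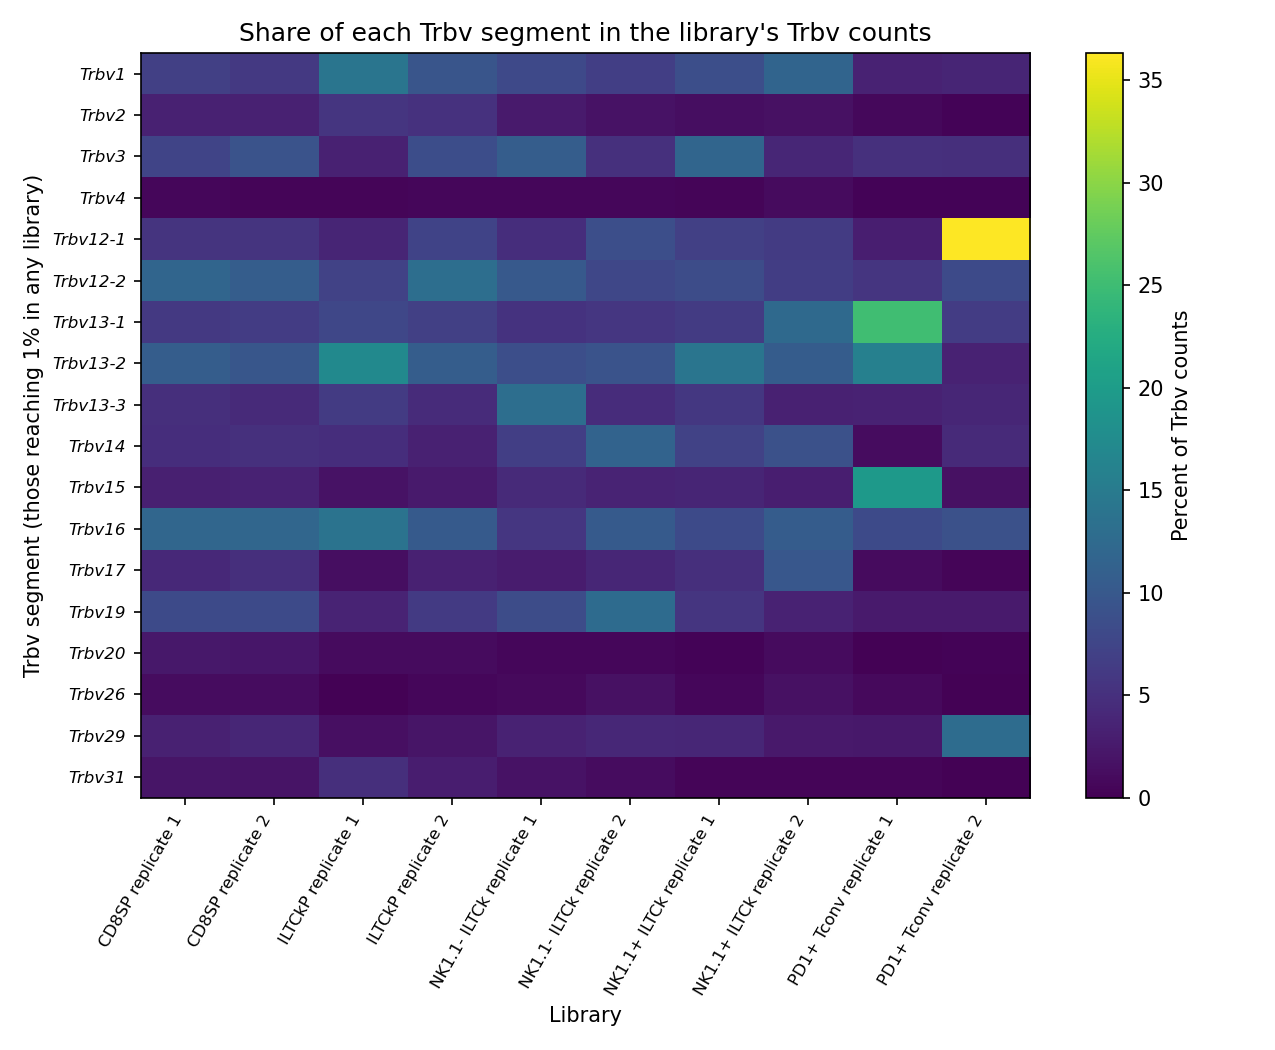
Share of each Trbv segment in the Trbv counts of each library (heat map, percent; rows are segments, columns are libraries). The largest share was 36.3% for Trbv12-1 in PD1+ Tconv replicate 2, and 12.02 to 17.2% in the thymic and ILTCk libraries.

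Transcripts of glands, which make secretions such as saliva, tears and milk, were abundant in the tumour table. The sum of 10 such transcripts, chosen after their values were seen, took 7.09 and 14.1% of the counts in NK1.1- ILTCk, 1.03 and 10.6% in NK1.1+ ILTCk, 0.438 and 26.5% in PD1+ Tconv, and no more than 8.62e-05% in any thymic library. Bpifa2, a salivary protein gene, alone took 19.5% of PD1+ Tconv replicate 2 and 4.20% of NK1.1- ILTCk replicate 1, and Mucl2, a mucin-like gene, 8.73% of NK1.1- ILTCk replicate 2 and 4.26% of NK1.1+ ILTCk replicate 2. Replicates of one group thus differed widely in these transcripts. Csn3 and Wfdc18, counted among the 10, also belong to the epithelial and mammary tumour list. They took 0.477 and 0.273% of NK1.1+ ILTCk replicate 1 and 0.175 and 0.0805% of PD1+ Tconv replicate 1, the libraries of the tumour table with the lowest sums. For Csn3 and Wfdc18, gland and tumour RNA were not told apart.

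**Figure D5:**
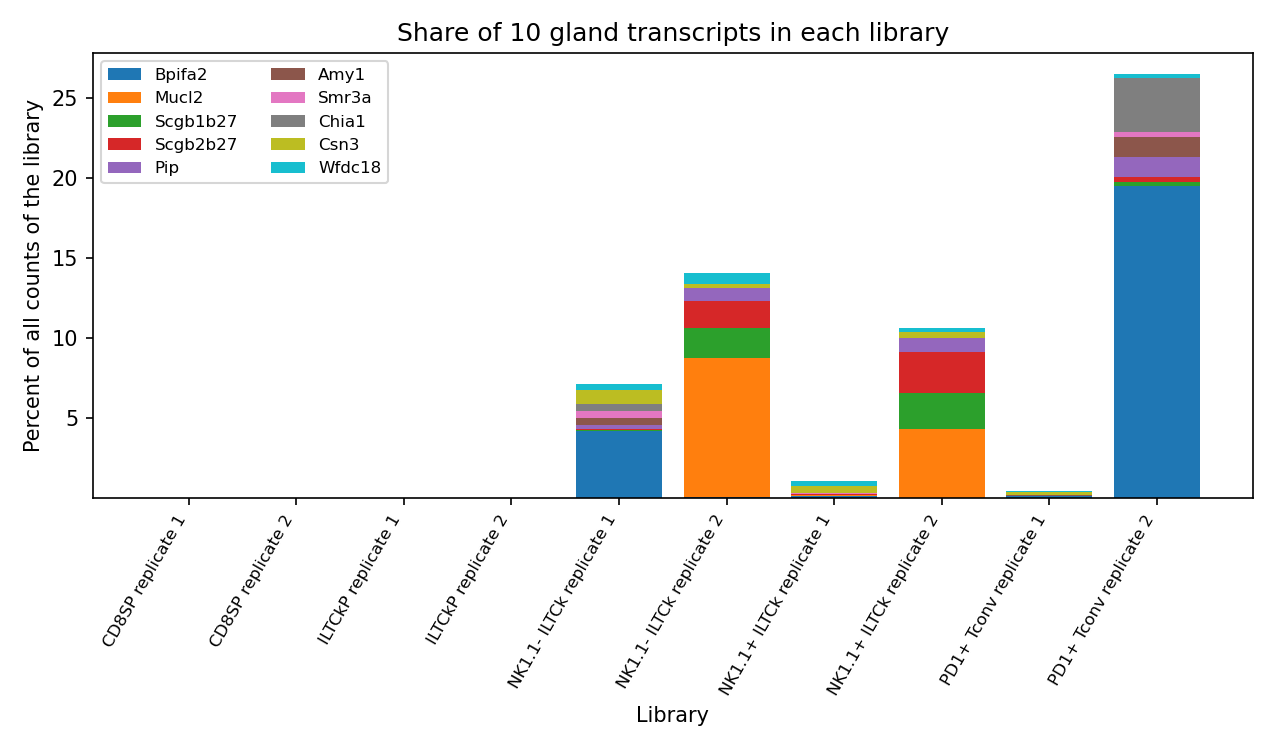
Share of 10 gland transcripts in all counts of each library (stacked bars, percent). The share reached 26.5% in PD1+ Tconv replicate 2, of which Bpifa2 made 19.5%, and stayed at or below 8.62e-05% in thymic libraries.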

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

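The restriction to genes expressed in the thymus and the list tests with a library left out were chosen only after the result was seen; the other settings were set before. The limits were 2 libraries per group, a wide spread in the tumour table and gland and myeloid transcripts in the sorted samples. In data simulated with the depth and spread of the tumour table, where few genes were changed, edgeR missed most changes of 8-fold. Part of the DESeq2 calls were false in those simulated data, and the false share in the real tables is not known. Leaving a library out leaves a group with a single sample, which is then assumed to vary like the other groups. The cause was not tested for any changed result.

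In ILTCkP against CD8SP the 689 calls became 2030 with DESeq2 and 2535 with no filter on low counts, and 592 to 7017 with a library left out (2812 without ILTCkP replicate 1 and 7017 without ILTCkP replicate 2). The 86 named genes kept their sign in every setting that measured them (84 with at least 50 counts); the 76 past the threshold became 56 with glmTreat or without CD8SP replicate 2 and 59 without CD8SP replicate 1.

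The 0 calls of edgeR in the tumour comparisons became, in NK1.1+ ILTCk against PD1+ Tconv, 1194 with DESeq2, 3 with limma-voom, 1249 with no filter on low counts, 18 among genes expressed in the thymus (3 higher, 15 lower) and 0 to 35 with a library left out (35 without NK1.1+ ILTCk replicate 1). In NK1.1- ILTCk against PD1+ Tconv they became 607 with DESeq2 and 799 with no filter, and in NK1.1+ against NK1.1- ILTCk 55 and 167. Genes called in the thymus and against PD1+ Tconv became 261 (NK1.1+) and 106 (NK1.1-) with DESeq2, of which 35 and 15, and 34 and 6, were called in opposite directions. RLE and upper-quartile scaling, at least 50 counts, glmTreat and the 4 compared libraries alone kept 0.

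Lists past the threshold were 13 in the thymus, 11 in NK1.1+ ILTCk against PD1+ Tconv, 17 in NK1.1- ILTCk against PD1+ Tconv and 8 in NK1.1+ against NK1.1- ILTCk. With an estimated correlation they were 0 in each, and with fry 11, 0, 1 (cytokines and chemokines) and 0. With a library left out the last had 6 to 19 lists (19 without NK1.1+ ILTCk replicate 2). The interferon-stimulated list in NK1.1- ILTCk against PD1+ Tconv had adjusted p from 3.96e-08 to 0.611.

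With a library left out, log2 fold changes that crossed 0 against PD1+ Tconv ran from -1.10 to 2.63 for Cd4 and -0.70 to 2.74 for Gzmb in NK1.1+ ILTCk, and in NK1.1- ILTCk from -0.90 to 3.19 for Klrb1c, -1.20 to 1.30 for Gzmb, -3.99 to 0.016 for Hic1 and -0.049 to 2.76 for Sox13. In NK1.1+ against NK1.1- ILTCk they ran from -1.38 to 1.21 for Cd8a and -0.27 to 2.20 for Gzmb. With limma-voom Cd4 was 0.25 and Cd8a -0.034.

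The shared replicate number as a block gave 2212, 755, 298 and 0 calls in the 4 comparisons, 207 and 58 genes called in both tables (27 and 18, and 25 and 4, of them in opposite directions), and values of 0.25 for Cd4 in NK1.1+ and 0.0019 for Gzmb in NK1.1- ILTCk against PD1+ Tconv. Same-numbered libraries deviated alike with correlations of 0.0918 in the thymus and 0.325 to 0.361 in the tumour table. In each tumour group replicate 2 had more gland transcripts and more Isg15 (25.69 and 139.9 CPM in NK1.1-, 30.79 and 145.9 in NK1.1+, 37.94 and 156.4 in PD1+). This is a hint from the data, as the labels name no shared batch.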

Other observations

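Among the tests in this part, only that of gland tissue RNA was written before its result was seen, and all others, with the thymic gene sets, were chosen only after the result was seen. The genes that were lower in ILTCkP than in CD8SP also lay lower in the ILTCk of the tumour table, where myeloid markers rose as well (median 4.11 in NK1.1+ and 2.02 in NK1.1- ILTCk against PD1+ Tconv) and CD3 and TCR genes were lower; whether dilution of T cell RNA lowers this set was not tested. Of 187 such genes measured in the tumour table, 130 had negative values in NK1.1+ ILTCk against PD1+ Tconv (median -0.61, camera adjusted p = 1.95e-09; adjusted p = 0.00389 with an estimated correlation), 126 in NK1.1- ILTCk against PD1+ Tconv (median -0.53, 1.19e-05; 0.00934) and 109 in NK1.1+ against NK1.1- ILTCk (median -0.22, 0.000461; 0.0194). Of 474 genes higher in ILTCkP, 304 had positive values in NK1.1+ ILTCk against PD1+ Tconv (median 0.48, 0.000771; adjusted p = 0.186 with an estimated correlation), 254 in NK1.1- ILTCk against PD1+ Tconv (median 0.10, 0.447) and 320 in NK1.1+ against NK1.1- ILTCk (median 0.42, 5.25e-05; adjusted p = 0.0902 with an estimated correlation).

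The ratio of Cd8b1 to Cd8a, which tells CD8αβ from CD8αα cells, was 1.44 and 1.42 in CD8SP, 0.489 and 0.318 in ILTCkP, 0.281 and 0.692 in NK1.1- ILTCk, 0.0393 and 0.138 in NK1.1+ ILTCk and 0.518 and 1.09 in PD1+ Tconv, so that NK1.1- ILTCk and PD1+ Tconv overlapped. Relative to 7 CD3 and TCR constant genes, Cd8a was level in the tumour table, at mean log2 ratios of 1.19 ± 0.17 in NK1.1- ILTCk, 1.22 ± 0.25 in NK1.1+ ILTCk and 1.16 ± 0.10 in PD1+ Tconv, while Cd8b1 was at 0.015 ± 0.75, -2.55 ± 1.03 and 0.75 ± 0.66. Gzmb stood at 1.90 ± 0.41, 3.02 ± 0.16 and 0.41 ± 1.29 on the same scale, and Pdcd1 at -2.83 ± 0.85, -4.67 ± 1.20 and 0.40 ± 0.08.

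Gland transcripts in the tumour table might come from gland tissue taken along with the tumour. The median of 14 gland markers reached 54.0 CPM in NK1.1+ ILTCk replicate 2 and was 0 in every thymic library, which fits RNA from gland tissue. Uneven gland RNA and a difference between the sorted groups cannot be told apart: the largest log2 difference between replicates exceeded that between group means by a median of 0.64 and in 11 of the 14 markers, but not in Aqp5, Prb1 and Ltf, and 2 libraries per group are too few to decide. The TCRβ and CD8α gates would remove gland cells, so free RNA or cell debris may be the carrier, which was not tested.

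Fcer1g was higher in ILTCkP and in NK1.1+ ILTCk, where myeloid cell RNA could be the source. In ILTCkP myeloid RNA as the whole source was excluded: the upper quartile of the myeloid markers' log2 fold changes was 2.45 against 7.12 for Fcer1g. Expression by the ILTCkP themselves and RNA of other lymphocytes, whose gamma-delta T cell and NK receptor genes also rose (medians 5.03 and 3.50), stay open and were not tested. In the tumour table myeloid RNA and expression by NK1.1+ ILTCk cannot be told apart. The ratio of Fcer1g to the median myeloid marker ranged over 10.3-fold. Only Cd14 (14.3-fold), S100a8 (31.7-fold) and S100a9 (98.8-fold) ranged further, the last from 0.255 CPM in PD1+ Tconv replicate 1. The other markers ranged over 1.51-fold (Apoe) to 7.09-fold (Csf1r). Both ends of the Fcer1g range lay in PD1+ Tconv. Fcer1g stood there at 184 CPM against a myeloid median of 12.3 CPM in replicate 1, and at 81.1 against 56.0 CPM in replicate 2. In NK1.1+ ILTCk it stood at 1446 against 288 and 1229 against 654 CPM. The range therefore cannot decide whether NK1.1+ ILTCk express Fcer1g. The CD45+ TCRβ+ CD8α+ gate would remove most myeloid cells, but median myeloid marker levels were 288 and 654 CPM in NK1.1+ ILTCk against 12.3 and 56.0 CPM in PD1+ Tconv.

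Lower T cell transcripts in NK1.1+ ILTCk than in PD1+ Tconv might follow from dilution by RNA of other cells. A smaller T cell share with all other cell types raised alike was excluded, as the lower quartile of the myeloid list lay 3.80 log2 units above the upper quartile of the stromal list. For the CD3 and TCR constant genes dilution by myeloid RNA and lower expression cannot be told apart: the NK1.1+ library with fewer myeloid transcripts had 1.43 times the level of the lower PD1+ Tconv library and the other 0.262 times, but the NK1.1- libraries, with fewer myeloid transcripts still (102 and 85.4 against 288 CPM), had lower levels of these genes (205 and 130 against 480 CPM). For the other 11 members of that list the ratio to the CD3 and TCR constant genes was taken. Such dilution alone would leave this ratio unchanged for genes that myeloid cells do not express. It would raise the ratio for genes that myeloid cells do express, and which members those are was not tested. The change in ratio over the 11 members had a median of -1.39 and an upper quartile of -0.59. Library medians did not overlap (-3.28 and -2.17 against -1.37 and -1.15), but 2 against 2 libraries fail to overlap by chance in 33.3% of cases. These values argue against such dilution as the whole source for the list as a set, without excluding it. Of the 11 members 9 were lower, and 7 did not overlap between groups. The change was -2.71 ± 0.22 for Cd5 and -3.30 ± 0.87 for Cd8b1. It lay within 2 standard errors of 0 for Cd28 (-2.80 ± 1.80), Icos (-2.21 ± 1.21), Cd2 (-0.68 ± 0.67), Ptprc (-0.50 ± 0.53) and Cd8a (0.05 ± 0.19), as for Cd4, which rose (2.26 ± 1.61).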
